A study of Homo sapiens with 11 samples.

How the data were processed

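Total RNA was measured by sequencing in 11 libraries of MDA-MB-231 cells, an epithelial breast cancer line derived from a metastatic pleural effusion. Cells received non-targeting siRNA (siNS, 100 nM, 2 libraries), a pool of siRNAs against BCL11A (siBCL11A, 100 nM, 3 libraries), a pool against MBNL1 (siMBNL1, 100 nM, 3 libraries) or both pools together (siB/siM, 50 nM each, 3 libraries). Per the labels, RNA was isolated at 48 h, ribosomal RNA was removed and stranded libraries were made. Groups were taken from the sample titles. The labels do not say whether the replicates are separate cultures; if they are not, the p-values measure only the spread between libraries, which may be technical.

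The authors deposited a table of RPKM values (reads scaled by gene length and by library size) for each library, made on genome build hg19. That table holds a separate block for each comparison with siNS, and each block lists 5360 genes for siBCL11A, 4690 for siMBNL1 and 6700 for siB/siM. Beside the RPKM values, the authors gave a log2 fold change, a mean level as log2 CPM and a p-value with its adjusted form. In the authors' deposited table the log2 fold change is siNS over knockdown, so its sign is opposite to the one used here. The largest adjusted p in the authors' deposited table is 0.04998, 0.0498 and 0.04998 in the 3 blocks, so the genes with values are those that passed the authors' own test against siNS. The ratio (fold change) column of the authors' deposited lists for siBCL11A, with 183 higher and 395 lower genes, is the ratio of mean RPKM. Those lists hold exactly the genes of the table with an adjusted p under 0.01, a mean of at least 2 RPKM in the higher group and a fold over 2. The authors' log2 fold change for siBCL11A follows library 1 alone (the SD of the difference across genes is 0.0057, against 0.117 for the mean of the 3 libraries). For siMBNL1 and siB/siM it follows the mean of the 3 libraries (SD 0.0054 and 0.0060). For this reason fold changes were recomputed here from the RPKM values. The authors also deposited 3 lists of cassette exons with an inclusion level, a fraction between 0 and 1, for siNS and for the knockdown. Each list gives 1 value per group, so the libraries of a group had been pooled or combined, no spread between replicates can be given, and the depth behind an inclusion value is unknown. The aligner, the counting program and the exon program are not given in the sources used here.

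The depth of each library was worked out from the RPKM values, because short RNAs of known length take values that are whole multiples of what 1 read contributes. A value was taken as whole within 0.05 reads. For siMBNL1 library 3 the size first came out doubled (99.8% of its counts were even) and was divided by 2. With these sizes, 45.9% of genes have whole read numbers in every library. The sizes lie between 20.04 M and 34.9 M reads per library (M, mega-reads). They are effective sizes behind the RPKM scale, not totals stated by the authors.

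The groups, gene lists, the rule for naming genes, the tests of the comparisons and most alternatives were chosen before the data were examined, and the closing section says which of its tests were chosen after. The plan named a count-based model first and, for a normalized unit such as RPKM, the linear model of limma on log2(RPKM + 1). Since the values are RPKM, the second was used (limma 3.58.1 in R 4.3.3) with a cell-means model of the 4 groups and empirical Bayes moderation with trend and robust options off. Genes needed a mean of at least 1 RPKM in at least 1 group, and all 8085 listed genes met this. A gene without a block in the table has no value in that group, and each gene was fitted on the groups it has. The prior had 4.83 degrees of freedom and a standard deviation of 0.0814 on the log2 scale. Adjusted p-values are Benjamini-Hochberg values from limma. They were computed as if 23227 genes had been tested, the number behind the authors' adjustment, with unlisted genes counted as not passing. A gene was called at an adjusted p under 0.05. The labels give the groups the same replicate numbers without saying what they share. Deviations from the group means correlated across genes with r over 0.1 for all 3 equal numbers of siBCL11A and siB/siM (0.33, 0.19 and 0.18). The libraries may therefore be paired in this comparison, which the labels do not say. Unequal numbers reached an r of 0.37, between siBCL11A library 1 and siMBNL1 library 2, so a pairing by equal numbers is not shown. However, siMBNL1 library 2 also had an r of 0.34 with siB/siM library 1. For siMBNL1 library 1, r was 0.16 with siBCL11A library 2 and 0.14 with siB/siM library 2, beside 0.13 with siB/siM library 3. Shared blocks in which siMBNL1 libraries 1 and 2 are exchanged therefore stay possible and were not tested. In the 5 other combinations of groups at least 1 equal number had a negative r. Log2 changes are differences of group means of log2(RPKM + 1), given with their standard error, and they understate the fold of genes at low RPKM. Levels are mean RPKM with the standard deviation over libraries. The comparisons were each knockdown with siNS, siB/siM with each single knockdown, and the non-additive contrast, which is the siB/siM change minus the sum of both single changes. The last 3 could use only genes listed in the blocks concerned, 4511, 3927 and 3149 genes.

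Gene groups were 34 lists written from textbook knowledge. They cover the siRNA targets, cell state, matrix, adhesion, cell cycle, stress, inflammation, metabolism, signalling, chromatin, RNA processing, motility, translation and markers of other cell types. A gene can be in more than 1 list. Lists with at least 3 measured genes were tested with camera in its pre-ranked form with a preset correlation of 0.01 between genes. Camera with an estimated correlation and fry were run beside it. P-values were adjusted over the lists of a comparison. The background of each list test is the listed genes of that comparison, which are themselves selected. For each list the count of members called among all genes is given, and also the count adjusted over the list alone. The genes named are MBNL1 and BCL11A where measured, then the 10 largest rises and 10 largest falls among called genes with at least 1 RPKM in the higher group, leaving out clone names. Up to 4 called members of each list, by smallest p, follow, or up to 2 uncalled members where a list has none. Exons named are the 8 largest gains and 8 largest losses in each list and up to 12 exons found in all 3 lists.

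Exon positions are hg19, counted from 1. GENCODE 29, which is on another build, was used only to say what an exon is, by gene symbol, exon length and the length of at least 1 of the introns beside it, so that no coordinates were converted. Exon directions were tested with two-sided exact binomial tests. The share of exons with a length divisible by 3 has an exact Clopper-Pearson 95% interval over exons. Membership of exon genes among called genes was tested with Fisher's exact test. For the closing section, 7-base words were counted in the longest annotated 3' UTR of each gene (at least 50 nt), and all 16384 words were compared between gene groups by a Mantel-Haenszel score within 25 strata of UTR length and GC content. The highest score was set against 20 scans with shuffled direction and against the coding sequence of the same transcripts. Permutation tests used 100000 draws. Simulations of unchanged genes drew independent normal values for libraries that share the siNS group, and the listing bound was the p-value at which each block ends; these simulations were added after seeing the data. For chance values shared through siNS, the expected number of such genes replaced the covariance as the test in the closing section, with limits of 0.1 and 0.5 kept, because the covariance had been simulated without the listing bound. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used.

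The fit was tested on simulated data of the same shape with 200 changed genes. Changes of 1 on the log2 scale were recovered for 100% of the changed genes in each comparison. At a change of 0.3, recovery lay between 22.4% and 47.8%, and at most 3 unchanged genes were called in a comparison. In simulated list data, 1 of 1 shifted lists and 0 of 30 unshifted lists were called by camera, and a planted word ranked 1 in the word scan.

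The alternatives tried were quantile normalization, no filter on low values, a pseudocount of 0.1, the replicate number as a block, leaving out each library in turn, fitting only the groups compared, an adjusted p under 0.01, added bounds on the log2 change, fry and an estimated correlation. For exons they were a larger difference in inclusion, coding exons only, matching by overlap or by gene, and 1 exon per gene. Adjustment over the listed genes only, a fit of genes listed in all 3 blocks, trend and robust moderation, and a background of listed genes for the exon genes were added after seeing the data. No count-based tool was run, since no counts per gene were used here. BCL11A itself has no value in any of the 3 blocks used here and is not analysed here. Some members of the gene lists that the naming rule selects are not reported here.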

Results

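RNA levels were measured in MDA-MB-231 breast cancer cells 48 h after transfection with non-targeting siRNA (siNS, n = 2), siRNA pools against the zinc finger repressor BCL11A (siBCL11A, n = 3) or the splicing regulator MBNL1 (siMBNL1, n = 3), or both pools together (siB/siM, n = 3). Single pools were given at 100 nM and the combination at 50 nM of each. The effective depth in mega-reads (M) was 20.04 M and 29.9 M in the siNS libraries, 26.8 M, 34.5 M and 33.0 M in siBCL11A, 34.7 M, 26 M and 25.8 M in siMBNL1, and 34.9 M, 32.7 M and 32.4 M in siB/siM. Levels are given as RPKM, mean ± SD over the libraries of a group, and log2 changes as estimate ± SE on log2(RPKM + 1). Values exist for 8085 genes that the authors listed as changed against siNS in at least 1 knockdown, so the shares of genes called below are shares of a selected table and not of the transcriptome. The 3149 genes listed for all 3 knockdowns had a standard deviation of log2 differences between libraries of the same group of 0.114 to 0.177.

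MBNL1 was lowered by its own siRNA and raised by the siRNA against BCL11A. The siNS libraries had 10.2 and 9.77 RPKM. After siBCL11A the 3 libraries had 27.7, 27.5 and 27.6 RPKM, a log2 change of 1.38 ± 0.08 (limma, adjusted p = 2.51e-07). After siMBNL1 they had 3.17, 3.52 and 2.55 RPKM (−1.44 ± 0.08, adjusted p = 3.79e-07), and after both pools 3.53, 3.65 and 3.56 RPKM (−1.26 ± 0.08, adjusted p = 5.32e-07). The level with both pools differed from that with siMBNL1 alone by 0.18 ± 0.07, which did not pass the test (adjusted p = 0.625), although each pool was then at the lower dose. In the authors' deposited table MBNL1 has log2 values, siNS over knockdown, of −1.47, 1.69 and 1.48. MBNL2, a paralog with overlapping targets, was at 7.73 and 7.23 RPKM in siNS, 6.06, 6.19 and 6.23 RPKM in siBCL11A, and 6.49, 6.16 and 6.54 RPKM in siB/siM. It has no value in siMBNL1, because it was not among the genes that passed the authors' test there. BCL11A is not among the genes with values here, in the siBCL11A block or the others, so its level is not analysed here and a fall of BCL11A itself is not shown.

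**Figure D1:**
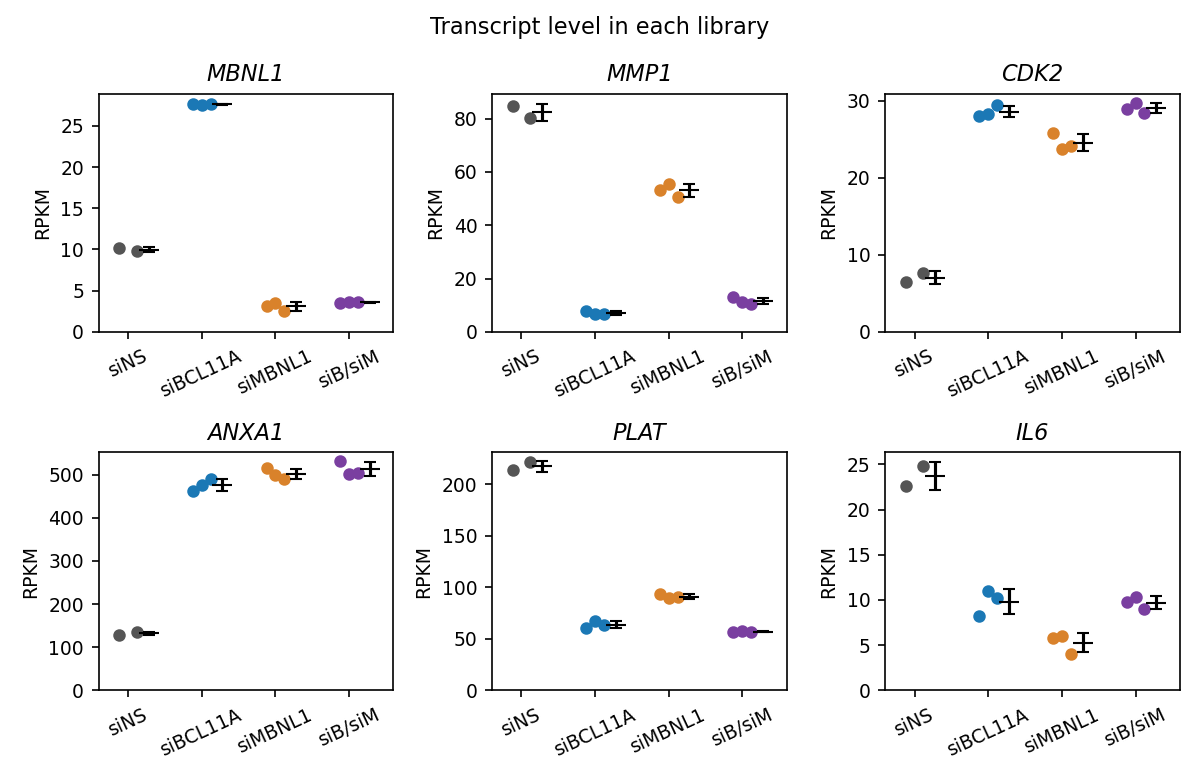
Level in RPKM (vertical axis, from 0) of MBNL1, MMP1, CDK2, ANXA1, PLAT and IL6 in each of the 11 libraries, by siRNA group. Points are libraries, and the horizontal mark and bar are the group mean and SD. MMP1 averages 82.3 RPKM in siNS, 7.05 in siBCL11A, 53 in siMBNL1 and 11.6 in siB/siM.

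The first comparison, siBCL11A with siNS, asks what follows siRNA against a repressor that the series title links to spread of breast cancer. The gene that fell furthest was MMP1, the interstitial collagenase, from 82.3 ± 3.12 RPKM (n = 2) to 7.05 ± 0.606 RPKM (n = 3; log2 change −3.37 ± 0.09, limma, adjusted p = 1.4e-09). PLAT, tissue plasminogen activator, fell from 217.5 ± 5.62 to 63.8 ± 3.24 RPKM (−1.75 ± 0.06). CDK2, a kinase of S phase entry, rose from 7.06 ± 0.874 to 28.6 ± 0.714 RPKM (1.88 ± 0.07), and ANXA1, a phospholipid-binding annexin, rose from 131.8 ± 3.39 to 475.6 ± 13.4 RPKM (1.84 ± 0.06). Among 5360 listed genes, 4780 passed the test, 2268 higher and 2512 lower in siBCL11A. Of all 5360, 5235 had no overlap between the libraries of the 2 groups, where chance gives 20% of unselected genes. The 5360 were listed by the authors' own test against siNS, so this separation largely follows from the listing. With a log2 change of at least 1 in addition, 94 genes were higher and 242 lower.

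Other large rises after siBCL11A were in RPS27L, a ribosomal protein paralog (log2 change 1.83), OTUD6B, a deubiquitinase (1.82), TTPAL (1.73), CENPQ, a kinetochore protein (1.71), PPME1, a phosphatase methylesterase (1.54), CDK6, the kinase partner of D-type cyclins (1.53), LMNB1, lamin B1 (1.49), and GEMIN5, a subunit of the SMN complex (1.47). Large falls were in IL24, a cytokine (−2.46), ST3GAL5, the sialyltransferase that makes ganglioside GM3 (−2.37), SERPINA1, a serine protease inhibitor (−2.36), LAPTM5, a lysosomal membrane protein (−2.29), SPINK4, a Kazal-type inhibitor (−2.28), and the adhesion receptor GPR116 (−2.16). The cystatins CST1 (−2.58) and CST4 (−2.41) and the trypsinogen PRSS2 (−2.35) fell as well, but each has close paralogs, and reads may be shared among family members.

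Cell cycle genes rose as a group after siBCL11A. All 25 measured G2/M and mitosis genes rose (median log2 change 0.69), among them HMMR (1.11), BUB1B, a spindle checkpoint kinase (0.99), UBE2C (0.77) and CCNB1, cyclin B1 (0.75). All 24 measured G1/S and DNA replication genes rose (median 0.61), with MCM7 (1.04), MCM10 (1.03), GINS1 (1.03) and CDC45 (0.95), parts of the replicative helicase or its loading. Both lists passed camera with an adjusted p of 1.35e-07, and both have an adjusted p = 0.449 with an estimated correlation. Of 11 genes of the histone list, 10 rose, including HIST1H4C (0.82), and 1 fell, H1F0 (−0.97), a replication-independent linker histone in a list otherwise meant for replication-dependent ones (camera adjusted p = 0.00658; adjusted p = 0.576 with an estimated correlation). Histone gene copies are nearly identical, so single copies are uncertain. Splicing factors had 17 of 23 members higher and 4 lower, such as CELF1 (0.55) and PTBP3 (−0.63). Their median was 0.27 (camera adjusted p = 0.0351; adjusted p = 0.449 with an estimated correlation), and the call ended without siNS library 1 (adjusted p = 0.0514) and with quantile normalization (adjusted p = 0.0798). Adjusted over the list alone, 18 splicing factors rose and 4 fell; the counts of the other 3 lists were the same.

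Protease, matrix, inflammatory and hypoxia genes fell after siBCL11A. Of 13 matrix proteases and inhibitors, 12 fell and 1 rose (median −0.76; camera adjusted p = 0.00185; adjusted p = 0.449 with an estimated correlation), with MMP14, a membrane collagenase (−1.18), and PLAUR, the urokinase receptor (−1.04). Collagens and laminins had 13 of 14 members lower, including COL5A1 (−1.25) and COL17A1 (−1.09), and 1 higher (median −0.66; camera adjusted p = 0.00606; adjusted p = 0.528 with an estimated correlation). Among 12 genes of the NF-kB and inflammatory list, all fell (median −0.67; camera adjusted p = 0.00433; adjusted p = 0.449 with an estimated correlation), such as IL1B (−1.28), IL6 (−1.20), PTGS2 (−1.04) and ICAM1 (−1.01). Type I interferon response genes had 17 of 20 members lower and 0 higher by limma, with IRF9 (−1.12), OAS2 (−0.88) and MX2 (−0.82). Their median was −0.55 (camera adjusted p = 0.00474; adjusted p = 0.450 with an estimated correlation), and adjusted over the list alone 18 fell and 1 rose. Hypoxia and glycolysis genes had 18 of 20 members lower and 1 higher (19 and 1 adjusted over the list alone), among them the glucose transporter SLC2A3 (−1.54), VEGFA (−1.26) and ANGPTL4 (−0.95). That list had a median of −0.58 (camera adjusted p = 0.000763; adjusted p = 0.566 with an estimated correlation). The metastasis list had 17 of 22 members lower and 3 higher (18 and 3 adjusted over the list alone), with a median of −0.72 (camera adjusted p = 0.00433; adjusted p = 0.449 with an estimated correlation). The protease, collagen and NF-kB counts were the same adjusted over the list alone. Markers of other cell types fell along with these groups: all 3 measured immune markers, CD14 (−1.38, 1.96 ± 0.235 RPKM in siNS), CSF1R (−1.17, 2.74 ± 0.582) and CD68 (−0.98, 56.8 ± 0.954), and all 4 measured endothelial and fibroblast markers, such as PDGFRB (−1.30, 2.67 ± 0.613). Camera gave these lists an adjusted p of 0.0559 and 0.0915.

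The other lists did not pass camera in siBCL11A, with adjusted p between 0.0559 and 0.909. Mesenchymal and EMT genes had 5 of 8 higher and 3 lower, with TAGLN (1.03), S100A4 (−0.93) and CDH11 (−0.85), while epithelial genes had 3 of 10 higher and 7 lower, with JUP, plakoglobin (−1.31), KRT19 (−1.20) and ST14 (−1.13). Integrins had 2 of 11 higher and 9 lower, and their members moved far apart, ITGB1 by 1.20 and ITGA2 by −1.55. Stem and basal markers had 1 of 8 higher and 6 lower, SOX4 among them (−1.60), and luminal markers 2 of 8 higher and 5 lower, SPDEF among them (−2.04). Targets of p53 had 5 of 8 higher and 3 lower, with CCNG1 (0.70) and TNFRSF10B (0.67). Stress response genes had 6 of 17 higher and 11 lower, with ATF4 (0.91), PPP1R15A (0.99) and DDIT4 (−0.89). Cholesterol synthesis had 2 of 10 higher and 7 lower, INSIG1 among them (−0.93). Of signalling lists, TGF-beta targets had 2 of 11 higher and 8 lower (ID3 1.09, TGFB1 −1.05), YAP and TEAD targets 7 and 4 of 11, WNT genes 2 and 6 of 9 (MYC 0.73, LRP5 −0.90), and NOTCH genes 2 and 1 of 3. Chromatin lists had 6 higher and 4 lower of 11 SWI/SNF subunits and 5 and 1 of 7 NuRD and corepressor subunits (SIN3B −0.72). Genes with exons known to depend on MBNL proteins had 5 of 25 higher and 14 lower, and cell motility genes 5 and 4 of 12, where ROCK1 rose (0.92). Ribosomal protein genes had 7 of 8 higher and 0 lower by limma, among them RPS3 (0.38), immediate early genes 5 and 5 of 11, and siRNA pathway genes 1 and 3 of 5 (XPO5 0.67, DICER1 −0.75). None of 5 nuclear genes of the respiratory chain passed limma over all genes, and 3 of them fell adjusted over the list alone. Only 1 erythroid gene, EPOR, was measured; it fell by 0.31, a call that ended without siNS library 1 or 2 or siBCL11A library 1 or 2. Adjusted over the list alone, falls became 9 for TGF-beta targets, 7 for WNT genes, 7 for stem and basal markers, 6 for luminal markers, 2 for NuRD subunits, 6 for immediate early genes and 4 for siRNA pathway genes, and the MBNL list had 6 rises and 17 falls. The NOTCH median was 0.24 with a mean of −0.21, and the motility median was −0.12 with a mean of 0.02, so the sign of these lists depends on the summary.

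Across lists, 10 of the 32 tested passed camera in siBCL11A, 4 upward and 6 downward. With an estimated correlation 0 passed, 1 at an unadjusted p under 0.05. Fry, which tests the members against no change and not against other genes, called 28. Since the genes were listed as changed against siNS beforehand, calls by fry against siNS say little.

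The second comparison, siMBNL1 with siNS, asks which transcripts change when MBNL1 is lowered. ANXA1 rose from 131.8 ± 3.39 to 501.5 ± 12.4 RPKM (log2 change 1.92 ± 0.06, limma, adjusted p = 6.78e-09), LMNB1 from 13.4 ± 0.844 to 53.2 ± 1.89 RPKM (1.91 ± 0.06) and CDK6 from 3.91 ± 0.0223 to 15.3 ± 1.96 RPKM (1.72 ± 0.08). IL6, an inflammatory cytokine, fell from 23.8 ± 1.55 to 5.29 ± 1.06 RPKM (−1.99 ± 0.14, adjusted p = 1.24e-06). MMP1 was at 53 ± 2.47 RPKM, against 82.3 ± 3.12 in siNS (−0.63 ± 0.09, adjusted p = 0.000194). Of 4690 listed genes, 4423 passed the test, 2119 higher and 2304 lower. The libraries of the groups did not overlap for 4678 of the 4690, against 20% by chance in unselected genes. This largely follows from the listing by the authors' test. A log2 change of at least 1 was met by 94 higher and 133 lower genes.

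CENPQ (1.68), CDK2 (1.67), OTUD6B (1.62), DEPDC1B, a regulator of adhesion and mitosis (1.48), and RPS27L (1.43) were the next largest rises after siMBNL1. Falls included SPINK4 (−2.39), ASB2, a ubiquitin ligase subunit (−1.90), RNASE1, a secreted ribonuclease (−1.81), SLC9A3R2, a scaffold of membrane transporters (−1.79), and the paralogous PRSS2 (−2.57), PRSS3P2 (−1.91) and CST4 (−1.80), whose reads may be shared. Small RNAs were among the largest changes too, MIR570 (1.78), SNORD81 (1.58, not called without siNS library 1), SNORA53 (−2.08) and MIR3134 (−1.88). They lie within other genes and are short, so their values are uncertain.

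All 26 G2/M genes rose after siMBNL1 (median log2 change 0.93), led by PLK1, polo-like kinase 1 (1.38), BUB1B (1.25), UBE2C (0.96) and CCNB1 (0.93). All 26 G1/S genes rose (median 0.70), with GINS1 (1.20), MCM10 (1.12) and RRM2, a ribonucleotide reductase subunit (1.11), and all 12 histone genes rose (median 0.73; HIST1H3B 0.90). Camera adjusted p-values were 2.82e-09, 4.15e-08 and 0.000302, against adjusted p = 0.553 for each with an estimated correlation. All 19 type I interferon genes fell (median −0.69; camera adjusted p = 0.000302; adjusted p = 0.553 with an estimated correlation), with IFI6 (−1.43), IRF9 (−1.10) and BST2 (−0.73). Of 14 proteases and inhibitors 13 fell and 1 rose (median −0.43; camera adjusted p = 0.0113; adjusted p = 0.553 with an estimated correlation), PLAT by −1.25 and TIMP3 by −0.90, while SERPINE2 rose (0.60). NF-kB genes had 12 of 14 lower and 1 higher (13 and 1 adjusted over the list alone; camera adjusted p = 0.0113; adjusted p = 0.553 with an estimated correlation), with IL1B (−1.36) and ICAM1 (−1.35). Hypoxia genes had 12 of 13 lower and 1 higher (camera adjusted p = 0.0117; adjusted p = 0.553 with an estimated correlation), with ALDOC (−1.18), ANGPTL4 (−1.02) and VEGFA (−0.81). Immune markers moved with the falling lists, all 3 measured lower (CD14 −1.07), as did all 3 endothelial and fibroblast markers (PDGFRB −1.08), with camera adjusted p of 0.108 and 0.129.

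Other lists did not pass camera after siMBNL1, and 24 of the 31 tested had an adjusted p between 0.0568 and 0.972. Splicing factors had 18 of 22 higher and 4 lower, with QKI (0.58) and SRSF1 (0.37), and metastasis genes 6 and 15 of 21. EMT genes had 3 of 7 higher and 4 lower, where VIM, vimentin (0.37), and TAGLN (0.68) rose and S100A4 fell (−0.88). Epithelial genes had 2 and 5 of 7, with JUP (−1.51) and KRT19 (−0.64). Integrins had 2 and 7 of 9 (ITGB1 1.18), collagens and laminins 2 and 7 of 11 (LAMC1 0.85, COL7A1 −0.81), and p53 targets 6 and 3 of 10 (CCNG1 1.06, MDM2 0.86). Stress response genes had 1 and 7 of 8, among them HSPA5, the ER chaperone (−0.83). Cholesterol synthesis had 5 and 1 of 8 (HMGCS1 0.48). TGF-beta targets had 2 and 8 of 11, YAP and TEAD targets 5 and 5 of 11, WNT genes 2 and 7 of 9 and NOTCH genes 3 and 2 of 6 (NOTCH2 −0.78). Stem and basal markers had 1 and 4 of 6 (SOX4 −1.43), luminal markers 1 and 6 of 8 (SPDEF −1.25), SWI/SNF subunits 5 and 2 of 7 and NuRD subunits 3 and 1 of 5. Among the genes with known MBNL-dependent exons, 8 of 21 rose and 12 fell. Motility genes had 4 and 8 of 15, with NEDD9 (−1.35), LIMK1 (−1.21) and MYL9 (−0.97). Ribosomal proteins had 2 and 0 of 3 by limma, immediate early genes 4 and 3 of 7 and siRNA pathway genes 4 and 1 of 5. A single respiratory chain gene was measured and did not pass, and 0 erythroid genes were measured. In counts adjusted over the list alone, motility genes had 11 falls, collagens 3 rises and 8 falls, p53 targets 7 rises, cholesterol genes 6 rises and 2 falls, and MBNL exon genes 13 falls. Counts of 8 further lists moved by 1 in this way: TGF-beta and YAP targets, NOTCH, stem and basal, and luminal genes, NuRD subunits, ribosomal proteins and the respiratory chain. For NOTCH genes the median was 0.06 and the mean −0.07, and for immediate early genes 0.25 and −0.08; camera pointed down for both. In this comparison 7 lists passed camera, 3 upward and 4 downward, 0 with an estimated correlation (1 at an unadjusted p under 0.05), and 24 by fry.

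The third comparison, siB/siM with siNS, asks what both pools together do. ANXA1 reached 512.8 ± 17 RPKM (log2 change 1.95 ± 0.06, limma, adjusted p = 4.2e-09), CDK2 29.1 ± 0.664 RPKM (1.90 ± 0.07) and LMNB1 48.3 ± 1.26 RPKM (1.78 ± 0.06), beside 475.6 ± 13.4 and 501.5 ± 12.4 RPKM of ANXA1 in the single knockdowns. MMP1 fell to 11.6 ± 1.20 RPKM (−2.73 ± 0.09, adjusted p = 4.2e-09) and PLAT to 57.1 ± 0.396 RPKM (−1.91 ± 0.06). Among 6700 listed genes 5819 passed, 3440 higher and 2379 lower. In 6672 of the 6700 the libraries of the groups did not overlap (20% by chance in unselected genes), which again largely follows from the listing. A log2 change of at least 1 was met by 139 higher and 203 lower genes. Rises of OTUD6B (1.81), RPS27L (1.76), CENPQ (1.72), TTPAL (1.66) and PPME1 (1.65) followed, with MIR570 (1.79) and MIR3648 (1.70, not called without siNS library 2), which are short and uncertain. Falls included LAPTM5 (−2.43), SPINK4 (−2.28), SERPINA1 (−2.21), IL24 (−2.13), LPXN, leupaxin, a focal adhesion protein (−2.13), and, among paralogs and small RNAs, CST1 (−3.11), CST4 (−2.92), PRSS2 (−2.42) and SNORA53 (−2.24).

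All 26 G2/M genes rose with both pools (median log2 change 0.82; PLK1 1.17, BUB1B 1.22), and all 26 G1/S genes (median 0.78; GINS1 1.19, MCM7 1.08). Camera gave both lists an adjusted p of 5.01e-07, against adjusted p = 0.297 and 0.289 with an estimated correlation. Histones had 12 of 13 higher and 1 lower (HIST1H3B 1.07; camera adjusted p = 0.00317; adjusted p = 0.431 with an estimated correlation). Targets of p53 had 8 of 10 higher and 1 lower (GADD45A 0.73, AEN 0.66; camera adjusted p = 0.0478) and splicing factors 24 of 32 higher and 5 lower (SRSF2 0.60; camera adjusted p = 0.0478); both have an adjusted p = 0.297 with an estimated correlation. Ribosomal proteins had 16 of 22 higher and 0 lower by limma (RPL8 0.41, not called without siNS library 1; camera adjusted p = 0.0477; adjusted p = 0.546 with an estimated correlation); processed pseudogenes share their reads. These last 3 calls lie at the threshold: leaving out any of 6 libraries ended that of p53 targets (siNS 2, siBCL11A 1 or 2, siMBNL1 3, siB/siM 2 or 3; adjusted p 0.0504 to 0.0601). Without siNS 1 or 2, siBCL11A 1 or 2, or siB/siM 2, splicing factors were not called (0.0505 to 0.066), nor were ribosomal proteins without siNS 1 (0.0998) or siB/siM 2 (0.0639). With quantile normalization splicing factors had an adjusted p of 0.191 and ribosomal proteins 0.976. With the replicate number as a block the adjusted p was 0.0551 for p53 targets, 0.0567 for splicing factors and 0.0584 for ribosomal proteins. With p adjusted over the list alone, 9 p53 targets, 27 splicing factors and 18 ribosomal proteins rose.

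By camera p, though not by median change, lists that fell with both pools were led by hypoxia genes. Of these, 18 of 22 were lower and 1 higher (SLC2A3 −1.40, VEGFA −1.24). Their median was −0.55 (camera adjusted p = 2.06e-05, adjusted p = 0.328 with an estimated correlation). Proteases and inhibitors had 11 of 12 lower and 1 higher (TIMP3 −1.25, MMP14 −0.91; median −0.75), and interferon genes 20 of 22 lower and 1 higher (IRF9 −1.12, OAS2 −0.86; median −0.51). Camera gave both an adjusted p of 2.74e-05, with adjusted p = 0.289 for both with an estimated correlation. NF-kB genes had 10 of 13 lower and 1 higher (IL1B −1.41, IL6 −1.21, PTGS2 −0.99; camera adjusted p = 0.00132; adjusted p = 0.299 with an estimated correlation). Metastasis genes had 17 of 25 lower and 4 higher (LTBP1 −1.30, NEDD9 −1.0; camera adjusted p = 0.000694), integrins 9 of 11 lower and 2 higher (ITGA2 −1.51, ITGB1 1.19; camera adjusted p = 0.0127), and stem and basal markers 6 of 9 lower and 1 higher (SOX4 −1.63; camera adjusted p = 0.0127). Each of these 3 has an adjusted p = 0.289 with an estimated correlation. Collagens and laminins had 9 of 14 lower and 4 higher (COL4A1 0.62; camera adjusted p = 0.0377; adjusted p = 0.431 with an estimated correlation). Markers of other cell types moved with them: all 3 immune markers fell (CD14 −1.33, CSF1R −1.07, CD68 −1.06; camera adjusted p = 0.0127) and all 4 endothelial and fibroblast markers (PDGFRB −1.27, KDR −0.65; camera adjusted p = 0.018), both with adjusted p = 0.289 with an estimated correlation. The second of these was not called with quantile normalization (adjusted p = 0.0524). Adjusted over the list alone, falls were 12 for NF-kB, 19 for hypoxia, 19 for metastasis, 8 for stem and basal and 10 for collagen genes, and rises 2 for hypoxia and 6 for metastasis genes.

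Lists not called with both pools had adjusted p between 0.0591 and 0.880. EMT genes had 5 of 10 higher and 5 lower (TAGLN 1.45), with a median of 0.00, a mean of −0.02 and a camera direction down. Epithelial genes had 6 and 8 of 14, stress response genes 7 and 8 of 17, cholesterol genes 5 and 6 of 12, TGF-beta targets 3 and 8 of 13 (ID3 1.03), YAP and TEAD targets 11 and 3 of 16, WNT genes 2 and 6 of 9 (MYC 0.79) and NOTCH genes 4 and 2 of 7. Luminal markers had 3 and 7 of 11 (SPDEF −1.76), SWI/SNF subunits 6 and 4 of 12 (BRD9 0.67), NuRD subunits 9 and 1 of 12, MBNL exon genes 11 and 15 of 31, motility genes 7 and 6 of 19, respiratory chain genes 2 and 0 of 5 by limma, immediate early genes 10 and 4 of 15 and siRNA pathway genes 3 and 3 of 7. For motility the median was −0.14 and the mean 0.02, and for siRNA pathway genes the median was 0.18 while camera pointed down. EPOR again was the only erythroid gene and fell by 0.32, a call that ended without siNS library 1 or 2 or siB/siM library 3. When adjusted over the list alone, YAP and TEAD targets had 13 rises, MBNL exon genes 18 falls, motility genes 8 rises and 8 falls, respiratory chain genes 5 rises, stress genes 10 falls, and TGF-beta targets 4 rises and 9 falls; 8 more lists moved by 1 or 2 genes. Of 32 lists 16 passed camera, 6 upward and 10 downward, 0 with an estimated correlation (2 at an unadjusted p under 0.05) and 28 by fry.

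**Figure D2:**
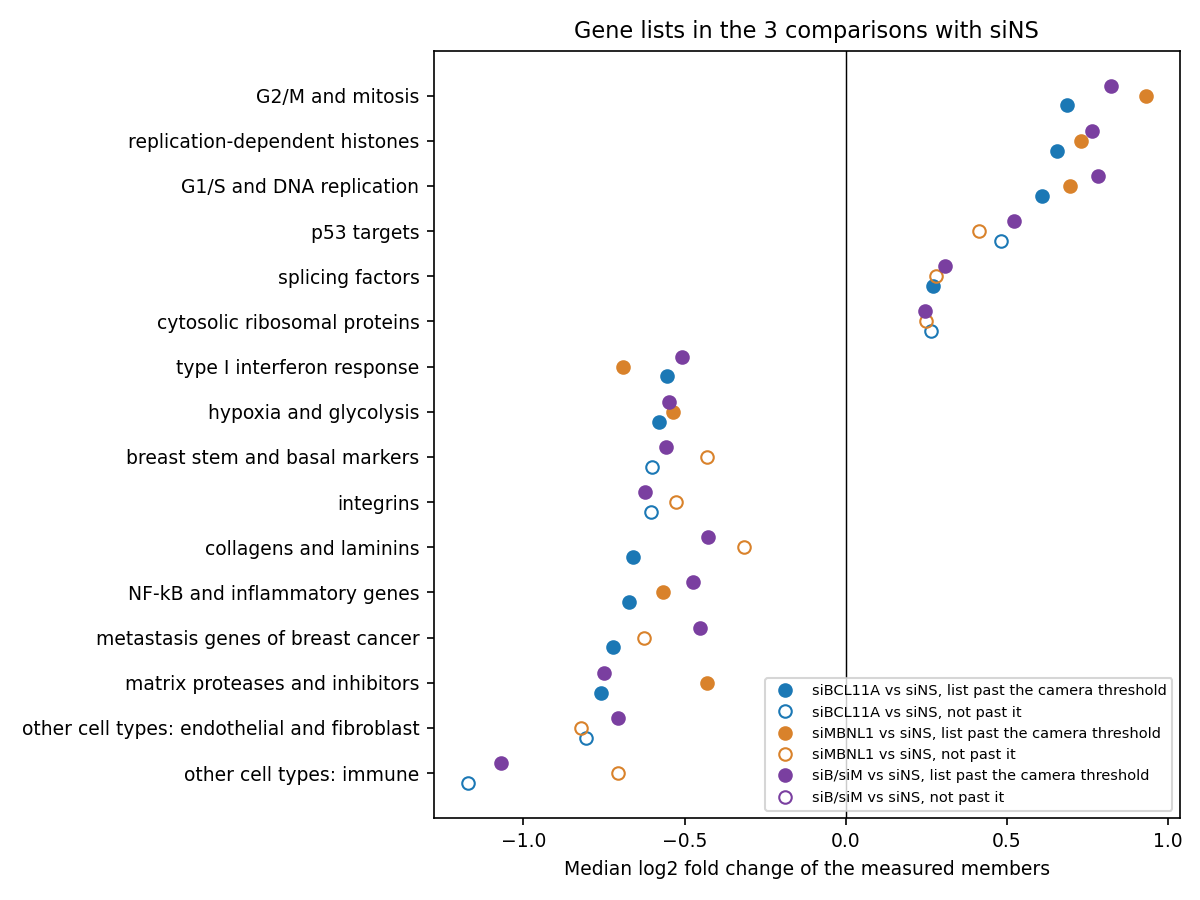
Median log2 change against siNS (horizontal axis, log2 of RPKM + 1) of the measured members of 16 gene lists (vertical axis) for siBCL11A, siMBNL1 and siB/siM. Filled points passed camera with the preset correlation and open points did not; the G2/M list lies at 0.69, 0.93 and 0.82 in the 3 comparisons.

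Of 7159 genes called in at least 1 knockdown against siNS, 2917 were called in all 3, and genes listed in 2 blocks mostly had the same direction in both. Over genes listed in both blocks, 3298 of 3376 (97.7%) had the same sign in siBCL11A and siMBNL1, 4479 of 4511 (99.3%) in siBCL11A and siB/siM, and 3876 of 3927 (98.7%) in siMBNL1 and siB/siM. Simulated groups without any change that share 2 control libraries had the same sign in 70.5%, 70.5% and 70.4% of genes, and in 100.0% of genes past the listing bound in both comparisons, so the shares do not test agreement. Such unchanged genes past both bounds would number 38.9, 48.9 and 44.9 among 23227. Pearson's r across genes was 0.91, 0.97 and 0.94, where genes are not independent replicates. Called higher in both were 1475, 2090 and 1891 genes, against 207, 336 and 314 expected for independent calls among 23227 genes. Called lower in both were 1586, 1984 and 1653, against 249, 257 and 236. All 8085 listed genes reach 1 RPKM. Where others of the 23227 are too low to be called, the expected numbers are too small and the excess is overstated. Of the 2917, 1463 were higher and 1425 lower in every knockdown. Since all 3 comparisons use the same 2 siNS libraries, which are too few to divide, part of this excess may come from shared controls. The simulated groups gave r of 0.600, 0.601 and 0.601 and a covariance of 0.00442, 0.00426 and 0.00449, or 0.0657, 0.0608 and 0.0651 past the listing bound in both, against 0.365, 0.377 and 0.359 observed. Opposite calls were few: 65 genes in siBCL11A and siMBNL1, MBNL1 among them, 3 in siBCL11A and siB/siM and 33 in siMBNL1 and siB/siM.

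The fourth comparison sets siB/siM against siBCL11A. The siBCL11A pool was at 50 nM in siB/siM and at 100 nM alone. A difference can therefore come from the siMBNL1 pool or from the lower dose of the siBCL11A pool, which cannot be told apart. The difference of means does not involve siNS, although the siNS libraries enter the pooled variance and the listing of tested genes. MBNL1 differed by −2.64 ± 0.07 (limma, adjusted p = 4.87e-09). COL18A1, the collagen that yields endostatin, rose from 27.9 ± 3.47 RPKM (n = 3) to 54.5 ± 4.26 RPKM (n = 3; log2 change 0.95 ± 0.09, adjusted p = 0.00424). MMP1 was higher, 11.6 ± 1.20 against 7.05 ± 0.606 RPKM (0.64 ± 0.08, adjusted p = 0.00684), a call that ended without siBCL11A library 2 (0.61, adjusted p = 0.0561). SERTAD2, a transcriptional cofactor, fell from 9.51 ± 0.557 to 4.60 ± 0.175 RPKM (−0.91 ± 0.09, adjusted p = 0.00268), and HDHD1, a pseudouridine phosphatase, by −0.81. Further differences were TAGLN (0.42), COL6A1 (0.55), COL5A1 (0.54), PLSCR4 (−0.69), PNPLA8 (−0.56), TIMP3 (−0.49), CAV1 (−0.40) and AHNAK (−0.40), and each of these calls ended without siBCL11A library 1, siBCL11A library 2 or siB/siM library 3. In total 92 of 4511 genes passed, 80 higher and 12 lower, and in 1540 of the 4511 the libraries did not overlap (10% by chance). At an unadjusted p under 0.05 there were 1173 genes.

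This count leans on single libraries and on scaling. It was 24 without siNS library 1, 28 without siNS 2, 9 without siBCL11A 1, 8 without siBCL11A 2, 12 without siB/siM 1, 15 without siB/siM 2 and 8 without siB/siM 3. Quantile normalization left 34 genes, 18 higher and 16 lower, so the excess of rises among the 92 depends on scaling, and the replicate number as a block gave 64. Collagens and laminins had 4 of 12 higher and 0 lower by limma (7 and 0 adjusted over the list alone; median log2 change 0.19; camera adjusted p = 0.0075), G2/M genes 1 of 25 higher and 0 lower (10 and 0 adjusted over the list alone; median 0.14; camera adjusted p = 0.00776), and histones 0 of 11 in either direction by limma (8 rises adjusted over the list alone; median 0.23; camera adjusted p = 0.0075). All 3 lists have an adjusted p = 0.893 with an estimated correlation, and the histone call ended without siBCL11A library 1 (adjusted p = 0.0696). No other list of the 30 tested passed, with adjusted p between 0.480 and 0.961; 0 passed with an estimated correlation, 0 at an unadjusted p under 0.05, and 8 by fry. G1/S genes had 0 calls among 24 over all genes and 5 rises adjusted over the list alone, and interferon genes 0 among 18 and 2. By p adjusted over the list alone, stress response genes had 3 rises and 2 falls, YAP and TEAD targets 2 and 3, and splicing factors 3 and 2 of 21. For 15 of the uncalled lists the median, mean and camera direction differed in sign, all with medians of at most 0.06 in size.

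The fifth comparison sets siB/siM against siMBNL1. Here the siMBNL1 pool was at 50 nM in siB/siM and at 100 nM alone. The siBCL11A pool and the lower dose of the siMBNL1 pool again cannot be told apart. MMP1 fell from 53 ± 2.47 RPKM (n = 3) to 11.6 ± 1.20 RPKM (n = 3; log2 change −2.10 ± 0.08, limma, adjusted p = 9.54e-08). ITGA2, the collagen-binding integrin subunit, fell from 46.6 ± 4.10 to 22.7 ± 1.35 RPKM (−1.01 ± 0.07), and TNC, the matrix glycoprotein tenascin C, from 13.6 ± 1.33 to 6.59 ± 0.262 RPKM (−0.94 ± 0.07). CYR61, a matricellular target of YAP, rose from 20.4 ± 0.674 to 51.0 ± 8.98 RPKM (1.27 ± 0.17, adjusted p = 0.00423), beside 30.7 ± 11.2 RPKM in siNS. IL6 was higher, 9.71 ± 0.716 against 5.29 ± 1.06 RPKM (0.78 ± 0.12, adjusted p = 0.00529). In total 454 of 3927 genes passed, 226 higher and 228 lower, and 1496 at an unadjusted p under 0.05. Libraries did not overlap in 1521 of the 3927 genes (10% by chance). The count of calls was 262 without siB/siM library 2 and 272 without siB/siM library 3, and 417 with the replicate number as a block.

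Other genes lower in siB/siM than in siMBNL1 were CST1 (−1.64) and CST4 (−1.12), which are paralogs. SLCO4A1, an organic anion transporter (−1.34), LAPTM5 (−1.22), GPR116 (−1.14), API5 (−1.01) and SLC17A5 (−0.94) were lower too. Rises were RRAD (1.07), SLC9A3R2 (1.07), PPME1 (1.03), ZNF768 (1.03), TOMM34 (0.94), TSC22D2 (0.86) and SERTAD2 (0.84). Proteases and inhibitors had 7 of 12 lower and 0 higher by limma (10 and 0 adjusted over the list alone), with PLAT (−0.66), MMP14 (−0.66) and PLAU, urokinase (−0.44). Their median was −0.29 (camera adjusted p = 1.07e-07; adjusted p = 0.424 with an estimated correlation). Hypoxia genes had 4 of 13 lower and 0 higher by limma (7 and 0 adjusted over the list alone), with SLC2A3 (−0.80), PFKFB4 (−0.46) and VEGFA (−0.43; median −0.22; camera adjusted p = 0.000418; adjusted p = 0.424 with an estimated correlation). Of 26 G2/M genes 2 fell, BIRC5, survivin (−0.44), and AURKA (−0.30), and 0 rose by limma. Adjusted over the list alone 8 fell and 1 rose (median −0.09; camera adjusted p = 0.0195; adjusted p = 0.968 with an estimated correlation), and the call ended without siMBNL1 library 2 (adjusted p = 0.065). Immune markers moved with these lists, 2 of 3 lower, CSF1R (−0.41) and CD68 (−0.36), neither called without siB/siM library 1 or 2, and all 3 adjusted over the list alone (camera adjusted p = 0.0216; adjusted p = 0.424 with an estimated correlation). That call ended without siMBNL1 library 3 (adjusted p = 0.06) and with quantile normalization (adjusted p = 0.123). Lists without a camera call, at adjusted p between 0.0805 and 0.977, held further called members. YAP and TEAD targets had 4 of 9 higher and 0 lower by limma, including ANKRD1 (0.50) and F3 (0.53), and motility genes 3 and 0 of 13, MYL9 (0.62), LIMK1 (0.56) and ZYX (0.46; 7 rises and 1 fall adjusted over the list alone). Other members were LAMC1 (−0.57) and COL17A1 (−0.52) among laminins and collagens, PTBP3 (−0.78) and CELF1 (0.48) among splicing factors, CXCR4 (−0.75) and LTBP1 (−0.53) among metastasis genes, ID3 (0.70), ATF4 (0.60) and MYC (0.48). Counts adjusted over the list alone held more: G1/S genes had 8 rises and 3 falls of 26 and metastasis genes 5 and 6 of 21. For 7 uncalled lists the median, mean and camera direction differed in sign, with medians of at most 0.13 in size. Of 31 lists 4 passed camera, all downward, 0 with an estimated correlation (3 at an unadjusted p under 0.05) and 8 by fry.

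The non-additive contrast asks whether the change with both pools equals the sum of the single changes, and doses differ (50 nM of each against 100 nM). For MBNL1 it was −1.21 ± 0.11 (limma, adjusted p = 3.65e-05), as siBCL11A raised and siMBNL1 lowered it. Of 3149 genes 2292 passed, 1251 above and 1041 below the sum, and 2926 had an unadjusted p under 0.05. Quantile normalization gave 1095 above and 1232 below, so the balance of directions depends on scaling. Regressed on the change with both pools across genes, the contrast had a slope of −0.81 and r of −0.92. A slope of −1 is what equal changes in all 3 knockdowns would give. The 2 quantities share libraries: simulated unchanged genes had a slope of −0.20 and r of −0.15, and those past the listing bound in all 3 comparisons a slope of −1.01 and r of −0.95, so slope and r are no test of non-additivity.

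Cassette exons came as 3 lists from the authors, each holding exons whose inclusion differed by at least 10.0 percentage points from siNS, with 1 pooled value per group and no replicates. Large shifts after siMBNL1 were seen in single exons. The 30-nt exon of MDM1 (chromosome 12, 68710361 to 68710390, hg19) fell from 91.3% to 22% inclusion after siMBNL1, an exon of STAU2, an RNA-binding transport protein (chromosome 8, 74439926 to 74440039), from 77.8% to 13.2%, and one of ETV1 in its untranslated part (chromosome 7, 14028893 to 14029089) from 84.3% to 33.3%. Exons of SYTL2 (chromosome 11, 85428526 to 85428573) and DMKN (chromosome 19, 36000813 to 36000863) rose from 36.2% to 81.5% and from 45.7% to 90.3%, and one of RIPK2 (chromosome 8, 90775057 to 90775210) from 14.6% to 57.3%. After siBCL11A, exons of C6orf52 (chromosome 6, 10687713 to 10687794), INF2, a formin (chromosome 14, 105181621 to 105181677), and PLD1 (chromosome 3, 171404475 to 171404588) rose from 11.4% to 53.3%, from 28.5% to 69.6% and from 14.2% to 48.8%. Inclusion fell in the 98-nt coding exon of RFESD (chromosome 5, 94988821 to 94988918) from 91.2% to 36.7%, in SH3D21 (chromosome 1, 36773519 to 36773564) from 72.8% to 26.1% and in DYNC1I2, a dynein chain (chromosome 2, 172569277 to 172569336), from 81.8% to 43.9%. With both pools, the 15-nt exon of ARHGEF10L (chromosome 1, 17961043 to 17961057) fell from 78.8% to 28.7%, that of MAP2K7 (chromosome 19, 7970693 to 7970740) from 62.6% to 25.1% and that of ATG16L1, an autophagy protein (chromosome 2, 234182367 to 234182423), from 64.4% to 28.9%. The 144-nt exon of NUMB (chromosome 14, 73745989 to 73746132) rose from 53.1% to 78.4%. Exons of NAV2 (chromosome 11, 20072835 to 20072879) and MAP3K9 (chromosome 14, 71202678 to 71202746) fell after siMBNL1 and after both pools, to 19.6% and 11.8% with siMBNL1 and to 20.3% and 12.5% with both pools, from 63.7% and 52.9% in siNS.

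The siBCL11A list held 107 exons, 49 with higher and 58 with lower inclusion (two-sided exact binomial p = 0.439), the siMBNL1 list 110, 41 higher and 69 lower (exact p = 0.00972), and the siB/siM list 146, 48 higher and 98 lower (exact p = 4.27e-05). Median changes were 18.9, 18.5 and 18.3 points in size. For siMBNL1 the excess of losses did not pass among exons changed by at least 0.2, 19 higher and 32 lower (exact p = 0.0919). Shared exons numbered 26 between siBCL11A and siMBNL1, 24 of them in the same direction, 32 between siBCL11A and siB/siM, 27 alike, and 54 between siMBNL1 and siB/siM, all 54 alike. All lists use the same siNS value for an exon in nearly every case and hold only exons past the listing bound. Simulated unchanged exons under these conditions moved the same way in 100.0% of draws, so these counts are no test of agreement. The draws used a standard deviation of 3.33 points per knockdown value and compared direction only, not the size of the moves. For shared exons the knockdowns differed from each other by a median of 3.17, 3.74 and 2.35 points, against 17.8, 18.4 and 18.9 points from siNS.

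All 3 lists held 16 exons in common, 14 of them with the same direction throughout. The 195-nt coding exon of SENP7, a SUMO protease (chromosome 3, 101117705 to 101117899), had 35.9% inclusion in siNS and 75%, 89.2% and 80.4% in siBCL11A, siMBNL1 and siB/siM. The 51-nt exon of MTA1, a NuRD subunit (chromosome 14, 105915696 to 105915746), had 73.3% in siNS and 39.7%, 54.7% and 49.6%, one of KIAA1109 (chromosome 4, 123147862 to 123147990) 89.5% and 62.3%, 65.3% and 60.5%, and one of ESYT2 (chromosome 7, 158545472 to 158545534) 36.2% and 15.5%, 14.7% and 16.5%. ITGA6 and KIF13A moved in opposite directions. The 130-nt, partly coding exon of ITGA6, the laminin-binding integrin subunit (chromosome 2, 173366500 to 173366629), had 38.0% in siNS, 55.0% in siBCL11A, 20.2% in siMBNL1 and 19.4% in siB/siM. The 39-nt coding exon of KIF13A, a kinesin (chromosome 6, 17790103 to 17790141), had 71.6%, 92.0%, 43.0% and 45.7%. Between siBCL11A and siB/siM alone, opposite moves were seen in MLLT4, afadin (chromosome 6, 168314083 to 168314103, 21 nt; 17.4% in siNS, 47.1% in siBCL11A and 5.96% in siB/siM), ZDHHC7 (chromosome 16, 85022369 to 85022479; 25.3%, 51.8% and 13.1%) and SEC31A (chromosome 4, 83763293 to 83763634; 71.5%, 56.8% and 83.1%).

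**Figure D3:**
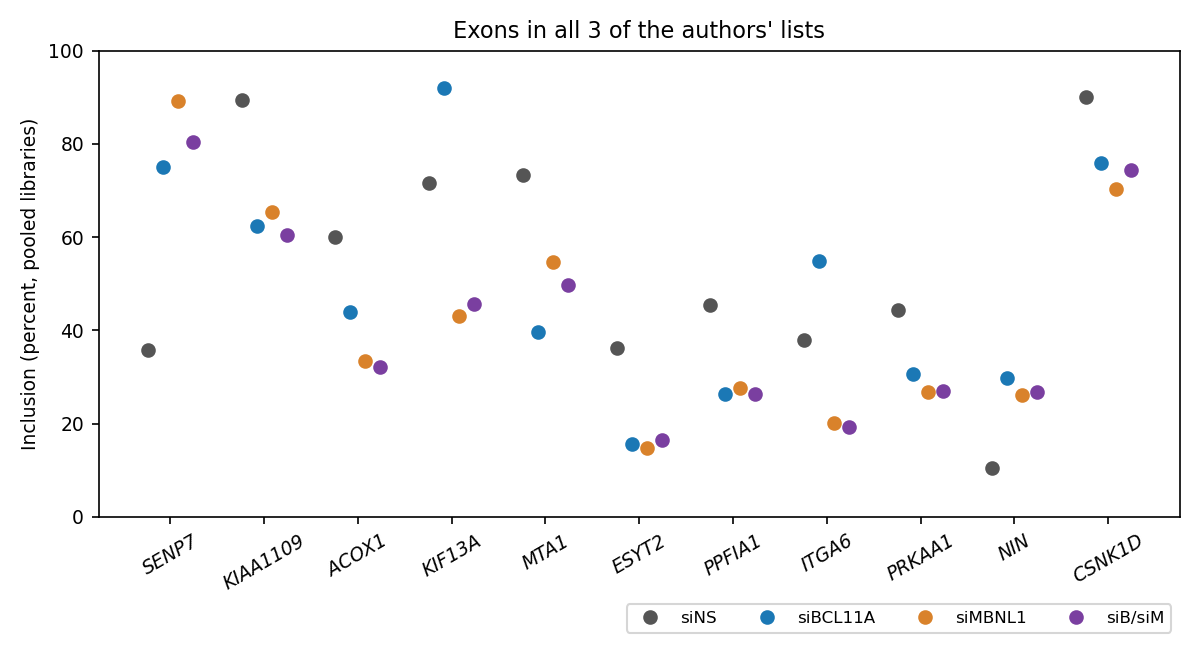
Exon inclusion in percent (vertical axis, pooled libraries, no error available) in siNS, siBCL11A, siMBNL1 and siB/siM for 11 exons found in all 3 lists (horizontal axis, by gene). ITGA6 and KIF13A lie above siNS in siBCL11A and below it in siMBNL1 and siB/siM; the other exons lie on the same side of siNS in all 3 knockdowns.

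Exon lengths were a multiple of 3 in 72 of 107 siBCL11A exons (67.3%, exact Clopper-Pearson 95% interval 57.5 to 76.0), 76 of 110 siMBNL1 exons (69.1%, 59.6 to 77.6) and 93 of 146 siB/siM exons (63.7%, 55.3 to 71.5). GENCODE exons of the same gene, length and at least 1 flanking intron length were found for 101, 100 and 135 exons (both introns for 93, 92 and 125), of which 70, 72 and 91 were coding. The share of genes with listed exons that were called did not pass a test of difference from other genes in the table: 46 of 78 against 59.1% of other genes for siBCL11A (Fisher's exact p = 1), 44 of 78 against 54.7% for siMBNL1 (Fisher's exact p = 0.82) and 68 of 101 against 72.0% for siB/siM (Fisher's exact p = 0.316).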

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

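The tests on values shared through the siNS libraries and on words in 3' UTRs were chosen only after the result was seen; the test of siNS depth was chosen before.

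The change with both pools differed from the sum of the single changes in 2292 of 3149 genes by the interaction contrast (limma, adjusted p under 0.05). The log2 difference from the sum was −1.21 for MBNL1. Above the sum were PRSS2 by 2.51, SPINK4 by 2.38, IL6 by 1.98, ST3GAL5 by 1.98, IL24 by 1.90, CST7 by 1.81, SLC9A3R2 by 1.80, PRSS3P2 by 1.79, EDN2 by 1.78 and RNASE1 by 1.75, all genes that fell in every knockdown. Below the sum were ANXA1 (−1.81), CENPQ (−1.67), CDK6 (−1.67), CDK2 (−1.65), OTUD6B (−1.64), LMNB1 (−1.62), RPS27L (−1.5), WEE1 (−1.42), TTPAL (−1.41) and CMTM6 (−1.41), all genes that rose in every knockdown. WEE1, the kinase that holds CDK1 inactive, was at 2.41 ± 0.233 RPKM in siNS (n = 2) and 7.88 ± 0.447, 8.12 ± 0.389 and 7.89 ± 0.327 RPKM in siBCL11A, siMBNL1 and siB/siM (n = 3 each). The doses differ between single and combined transfection, and no dose series was measured.

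These values reflect a wider pattern: genes moved the same way against siNS whichever pool was used, although MBNL1 itself moved up with one and down with the other. Unchanged genes expected past the listing bound for siBCL11A and siMBNL1 were 0.0115 of the genes listed for both (38.9 of 3376). Chance at the spread seen between libraries, shared through siNS, would thus account for few of these genes. The authors' threshold itself caps how many unchanged genes can pass, so this ratio could not have reached the limit of 0.1 here. A deviation common to both siNS libraries is not part of that spread and was not tested. The labels do not say whether replicates are separate cultures. The ratio replaced a test on covariance, which does not decide. The simulated covariance was 0.0121 of the observed one without the bound and 0.180 with it, between the limits of 0.1 and 0.5. The second value covers only unchanged genes past both bounds, so it is not a share of the pattern explained. For the lower depth of siNS library 1, siB/siM changes against siNS library 2 had a slope of 0.964 on those against library 1. This argues against depth as the cause, although the authors' listing favours genes on which both siNS libraries agree. A seed-like effect of the siNS duplex may account for part of the rises: AAGCCTT ranked first of all 7-base words in 3' UTRs of genes that rise over those that fall (z = 10.0, 433 genes against 334 expected, shuffled maximum 4.39), with z = 5.07 in coding sequence, which is lower but also above that maximum. Its core AGCCTT was in 59.8% of the 1467 searched rises (exact 95% interval 57.2 to 62.3) and in 38.7% of falls. Within strata of UTR length and GC content, 877 rises had it against 753 expected. Among rises, size hardly followed the number of sites (medians 0.52, 0.52 and 0.54 with 0, 1 and 2 or more). Within strata, rises with 1 and with 2 or more sites lay 0.02 and 0.05 over those with 0. Choosing genes by their rise can hide such a relation. Over all searched genes listed for all 3 knockdowns, median log2 changes were −0.38, 0.28 and 0.41 with 0, 1 and 2 or more sites. Less the median of each stratum they were −0.07, 0.01 and 0.15. The word was chosen on rises over falls of these genes, so these medians largely restate that choice. Seed-like effects as the whole cause and as part of it cannot be told apart, because the bound of 60 was set after the value was seen and lies within that interval, and genes without a site could rise indirectly; the words came from exploratory scans over several gene sets, the siRNA sequences are not analysed here, and a shared biological response to the 2 pools stays open and untested, since no untransfected group or second control siRNA was part of the design.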

How the results depend on the processing

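Adjustment over listed genes only, fits of genes listed in all 3 blocks, trend and robust moderation, and the listed-gene background for exon genes were chosen after seeing the data. Named genes gave 11030 values for 588 results over all alternatives: 10559 kept direction and side of the threshold, 76 gained a call, 0 reversed and the rest lost it (limma); of 600 values for 40 called lists, 67 lost the call. The counts against siNS (4780, 4423, 5819) stayed within 1.5 times except in fits of genes listed in all 3 blocks, which test fewer genes (3003 for siBCL11A and 2963 for siB/siM), and under added bounds on log2 change, which lower counts by construction: at least 1 left 336, 227 and 342, and the lower bound (a fold of 1.5) left 1675, 1288 and 1746. For siB/siM with siBCL11A the 92 became 34 with quantile normalization, 47 with pseudocount 0.1, 456 adjusted over listed genes only, 24 in genes of all 3 blocks, 165 with trend and robust, 8 at adjusted p under 0.01, and 1 and 13 with these bounds. For siB/siM with siMBNL1 the 454 became 993 over listed genes only, 214 at 0.01, and 14 and 96 with the bounds; the 2292 non-additive genes became 201 and 1124. Over left-out libraries the counts ran from 3869 to 4819, 3139 to 4455, 4227 to 5938, 8 to 126, 262 to 453 and, for the contrast, 1745 to 2252; a lone siNS library is assumed to vary like other groups. Lists called ran from 10 to 11, 7 to 8, 13 to 16, 2 to 3 and 3 to 5. With replicate number as a block, counts were 4756, 4253, 5406, 64, 417 and 2260 and lists 10, 8, 13, 3 and 4. The median r across genes was −0.05 over all 15 pairs of libraries with the same number. For siB/siM with siBCL11A no list or gene named there changed its call under this block. A block with siMBNL1 libraries 1 and 2 exchanged was not run. An estimated correlation called 0, 0, 0, 0 and 0 lists (1, 1, 2, 0 and 3 at an unadjusted p under 0.05) and fry 28, 24, 28, 8 and 8. Quantile normalization moved the median contrast by 0.109. Among siMBNL1 exons changed by at least 0.2, 37.3% rose (exact p = 0.0919), and 87.5% of 8 shared with siBCL11A agreed, fewer exons. Coding exons alone were a multiple of 3 in 80%, 81.9% and 79.1%. Apart from tests on fewer genes, exons or libraries and stricter bounds, the cause was not tested. The filter on low values removed no gene, so lifting it tests nothing. A count-based tool, the stricter part of the exon lists by the authors' p, list settings for the authors' calls only, and the contrast in compared groups only were not run. Depth of 20.04 M to 34.9 M reads limits low genes, and exon depth is unknown.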

Other observations

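Among the tests in this part, those on the opposite exons, on word shifts between libraries of 1 group and on other splits of the libraries were chosen only after the result was seen, as were the genes named in the next paragraph; the other tests were chosen before.

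The single knockdowns moved 65 genes in opposite directions against siNS, 32 higher and 33 lower in siBCL11A. CDKN1A, the p21 inhibitor of cyclin-dependent kinases, was at 31.6 ± 2.21 RPKM in siNS (n = 2), fell to 22.1 ± 0.873 in siBCL11A (n = 3) and rose to 45.2 ± 4.14 in siMBNL1 (n = 3). TNC went from 9.06 ± 0.393 to 5.83 ± 0.304 and to 13.6 ± 1.33 RPKM. ELL2, a transcription elongation factor, went from 19.1 ± 0.231 to 8.65 ± 0.255 and to 23 ± 1.26 RPKM, and PNP, the purine nucleoside phosphorylase, from 19.5 ± 0.690 to 11.3 ± 0.973 and to 28.5 ± 0.841 RPKM. In the other direction, POLR3D, a subunit of RNA polymerase III, went from 12.1 ± 0.752 up to 20.1 ± 0.681 and down to 8.62 ± 0.738 RPKM, PLAC8 from 59.3 ± 3.81 to 78.8 ± 3.28 and 38.6 ± 2.54 RPKM, and NOTCH2, whose rise was not called when siNS 1 or 2, siMBNL1 1 or any siBCL11A library was left out, from 42.2 ± 0.663 to 50.0 ± 1.09 and 24.1 ± 2.11 RPKM. Of the 38 such genes with a siB/siM value, 29 were called there, 27 in the direction of siBCL11A and 2 in that of siMBNL1. The rest of the 65, CDKN1A, PLAC8 and NOTCH2 among them, did not pass the authors' test of siB/siM against siNS. Genes whose 2 changes offset each other would be missing in this way. The 27 therefore do not show which pool prevails across the 65. DUSP6, a phosphatase that acts on ERK, fell in all 3 comparisons, from 56.0 ± 0.218 RPKM in siNS to 25.3 ± 0.474, 36.5 ± 2.74 and 26.4 ± 0.998 RPKM in siBCL11A, siMBNL1 and siB/siM.

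Genes that differ between the pools were searched for words that could mark seed-like effects of each pool. Among genes lower in siBCL11A than in siMBNL1 libraries 1 and 2, AGAATAA led all words (z = 7.46, shuffled maximum 4.80). In siB/siM minus siMBNL1 library 3, held out of that choice, the 862 genes with it differed by −0.0378 from the 2905 without it. Medians were 0.0556 and 0.0875, with 496 of 862 below the median of the others (permutation p over genes = 1e-05, the smallest possible). Part of the difference may be a seed-like effect of the siBCL11A pool. The contrast of siB/siM with siMBNL1 library 3 carries that pool too. Any other effect of the pool on these genes would recur there and cannot be told apart. Each siB/siM library gave −0.0414 to −0.0312 against that 1 library, while 9 pairs of libraries of 1 group differed by at most 0.0115; the word family had been seen in an earlier exploratory scan, and the shift is small beside the changes of named genes. For the siMBNL1 pool, CGTAGGA led with z = 4.41, under the shuffled maximum of 5.39; the 75 genes with it differed by −0.0442 from the 4273 without (medians −0.0204 and 0.0309; 49 of 75 below the median of the others; permutation p over genes = 0.012), which met the bound set before, but a condition that the word exceed the shuffles was added after the value was seen, and an earlier scan had led with ACCCAGA, here rank 3. This effect and chance choice of a word cannot be told apart, because no word stands above the shuffled scans and libraries of 1 group differed by up to 0.0320.

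Exons listed for both siBCL11A and siMBNL1 mostly moved the same way. If the opposite MBNL1 levels were the cause, these exons would move in opposite directions, and 7.69% did (2 of 26, ITGA6 and KIF13A). That count restates the pattern. Unchanged exons past the listing bound in both lists also move alike, so the count does not decide on MBNL1. Without siNS the 2 knockdowns differed by a median of 3.17 points (under 10 in 20 of 26). Opposite moves past the listing bound need at least 20, but these exons too were chosen by their distance from the same siNS value. The shared siNS inclusion values and a common response cannot be told apart by direction, because each list holds 1 pooled siNS value. Simulated unchanged exons past the listing bound in both lists moved the same way in 100.0% of draws, an outcome that the construction made foreseeable. Those draws had a standard deviation of 3.33 points per knockdown value, and the size of the moves was not compared. The exons of ITGA6 and KIF13A lay above siNS where MBNL1 was higher than in siNS, and below siNS where MBNL1 was lower. They are hypotheses for exons that respond to MBNL1 directly, untested here for want of replicate values.

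For the comparisons of siB/siM with each single knockdown, the libraries were also divided in other ways. In siB/siM with siBCL11A, 1 of 10 splits of the 6 libraries gave at least 92 genes, the real one, and the highest other gave 0 by limma (68 to 361 at an unadjusted p under 0.05, against 1173); the 3 others that part each number of siBCL11A from the same number of siB/siM gave 0 (68 to 143 unadjusted). In siB/siM with siMBNL1, 1 of 10 gave at least 454, the real one, and the highest other 0 (93 to 406 unadjusted, against 1496). With 10 splits a share under 0.05 cannot be reached.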
